A study of Mus musculus with 4 samples.

How the data were processed

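RNA-seq was available for natural killer (NK) cells isolated from the decidua, the maternal lining of the pregnant uterus, of wild-type mouse dams at embryonic day 13.5 (E13.5). Isolation took place 24 hours after an injection of saline or of polyIC, a synthetic double-stranded RNA that is commonly used to mimic a viral infection. There were 4 libraries in 2 groups, with n = 2 for saline and n = 2 for polyIC. Groups and replicate numbers were taken from the sample labels. Polyadenylated RNA was purified with poly-T beads before library preparation, per the labels' protocols. How the NK cells were isolated, whether the libraries mark strand, and whether the libraries of a group came from separate dams are not given in the sources used here. The p-values therefore measure the spread between these libraries, which may be technical.

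CASAVA, Trimmomatic 0.36, HISAT2 2.0.5 and featureCounts 1.5.0-p3 are named in the submitters' processing notes, with mouse genome build GRCm38 (mm10). The values used here are the RPKM values deposited by the authors in a table of 29041 genes, with the coordinates and the exon length of each gene in the columns that featureCounts writes, per the file headers. No gene in the table was at 0 in all 4 libraries. RPKM multiplied by exon length in kilobases summed to 1000000 in each library, so the authors' scaling was relative to the reads assigned to the listed genes. The same product was a whole multiple of 1 step in each library for 100% of the values (tolerance 0.01 of a step), which gave back whole reads. The totals were 26294620 and 25286670 reads in saline replicates 1 and 2, and 28159516 and 32908830 reads in polyIC replicates 1 and 2. At these depths, 3 reads on a gene with 1 kilobase of exons were worth 0.0912 to 0.119 RPKM. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 33.3 for the saline pair and 115 for the polyIC pair, so no pair was merged as copies of a single library. This does not show that the libraries came from separate animals.

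Gene names were used as the table gives them. GENCODE M21 held 27826 of them, another 358 matched an older symbol in RefSeq, and 832 matched neither. Chromosome, start and end were the same as in GENCODE M21 for 84.4% of the genes. In the table, 25 names had been turned into dates by spreadsheet software, with 2 repeats among the names, and these genes are not named here. Every column of per-sample values was used.

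Genes with a mean RPKM of at least 1 over the 4 libraries were tested (13523 genes, 10654 of them protein-coding). The 2-sided moderated test of limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) was run on log2(RPKM + 0.5), with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are polyIC minus saline on the log2(RPKM + 0.5) scale, which understates the change of low genes, and are given with the standard error (SE) of the moderated fit. Levels are mean RPKM ± SD. RPKM values are not read counts, so no count model was used as the main test. Before the data were examined, 38 gene lists (808 genes) were fixed from the tissue, the cell type and the treatment, and 36 of them had at least 5 tested members. They cover interferon responses, antigen presentation, RNA sensing, NK receptors, regulators, effectors and cytokines, growth factors, cell cycle, metabolism, stress and signalling responses, and markers of other cells of the decidua and placenta. Each list was tested against all other genes with camera in limma at a preset correlation between genes of 0.01, and again with camera at an estimated correlation. The rotation test fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, was run as well. Benjamini-Hochberg adjustment was over the 36 lists. Some genes stand in more than 1 list, most of all in the circulating NK list, where 10 of 15 tested members stand in another list as well.

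The genes named in the text follow a rule that was also fixed before the data were examined. In each direction it takes the 12 protein-coding genes with the largest change among those past the threshold, filled to 12 by the smallest p among genes with an absolute log2 fold change of at least 1. Predicted genes with Gm and Rik names were left out there. It adds up to 4 members with the smallest p in each list, 15 fixed genes, the 5 most abundant genes and the 2 most abundant members of each list of other cell types. Genes outside the rule are said to be so where they appear. Genes whose exons overlap another listed gene are uncertain, because the strand setting of the counting is not given. Near-identical genes (the Gbp, Klra, Gzmd to Gzmg, Prl and Psg families and the Tgtp pair) could exchange reads in the same way.

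The fit was tested on simulated data with the spread of these libraries, in 10 simulations of the comparison of polyIC with saline over 13523 genes. The share of changed genes recovered at the adjusted threshold was 1% for 2-fold, 39% for 4-fold, 70.6% for 8-fold and 92% for 32-fold changes. Among unchanged genes 0.0399% passed. A list shifted by 1 on the log2 scale was called in 10 of 10 simulations, and none of 350 unchanged lists was called, with no correlation between genes simulated.

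Alternatives fixed before the data were examined were other pseudocounts, other filters on low values, other scalings, other variance models, the replicate number as a block, protein-coding genes only, a fold-change threshold and leaving out each library in turn. When a library was left out, the lone library of its group was assumed to vary like the other group. Limma voom on the recovered reads was added after the data were seen, and so was the list of ribosome biogenesis genes. Checks of GC content, gene length, depth and other splits of the libraries used the longest GENCODE M21 transcript per symbol for GC content, loess curves, and a thinning of the recovered reads to 25286670 per library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.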

Results

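The data set compares the transcriptome of decidual NK cells from dams given polyIC with that of cells from dams given saline, at E13.5 and 24 hours after the injection. Each group held 2 libraries, with 25286670 to 32908830 reads assigned to genes per library. Between 23615 and 25294 genes were above 0 per library. On log2(RPKM + 0.5), Pearson's r across the 13523 tested genes was 0.972 for the saline pair, 0.941 for the polyIC pair and 0.938 to 0.948 between groups (genes are not independent replicates). The first principal component held 44.5% of the variance and parted the groups. The second component held 38.1% and parted polyIC replicate 1 (42.5) from polyIC replicate 2 (−31.5), with both saline libraries between them.

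The comparison asks how polyIC given to the dam changes gene expression in isolates of decidual NK cells. In saline libraries the macrophage markers Apoe and Lyz2 were at 1805 ± 108 and 874 ± 53 RPKM, and the NK receptor gene Ncr1 at 52.6 ± 12.5. The cells in which a gene changed therefore cannot be told from these values. Cxcl9, which encodes an interferon-gamma-induced chemokine that attracts lymphocytes, rose from 1.46 ± 0.17 to 66.8 ± 4.6 RPKM (SD, n = 2 per group), a log2 fold change of 5.10 ± 0.15 (SE). It was the sole gene of 13523 past the threshold (adjusted p = 0.0356, limma), and both polyIC libraries lay above both saline libraries. Cxcl9 lies on chromosome 5 from 92321347 to 92328079 (GRCm38), on the minus strand. At an unadjusted p under 0.05, 1121 genes were higher and 1031 lower, a total of 2152 where chance gives about 676. Among these, 231 higher and 241 lower genes differed by at least 1 on the log2 scale. The Cxcl9 call was lost with no filter on low values (adjusted p = 0.0781), without the variance trend (0.068), with voom on recovered reads (0.0585) and when any 1 library was left out (0.103 to 0.827). Its adjusted p ranged from 0.0202 to 0.827 over all alternatives, and its log2 fold change from 4.79 to 5.51. In a fit without 1 library, the residual spread comes from the pair of the other group alone. The median within-group SD on the log2 scale was 0.1245 for the saline pair and 0.1909 for the polyIC pair. Counts of genes at the unadjusted threshold in such fits therefore depend on which pair is left.

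The genes with the next smallest p among those higher after polyIC did not pass the adjusted threshold and are given as values. Saa3, an acute-phase serum amyloid, was at 0.769 ± 0.200 RPKM in saline and 26.7 ± 0.1 in polyIC libraries, a log2 fold change of 4.43 ± 0.18 (adjusted p = 0.0632, limma). With a pseudocount of 1 it passed (adjusted p = 0.0494, in a range of 0.0494 to 0.827 over the alternatives that test all genes), and so it did among protein-coding genes alone. Interferon-inducible GTPases stood high on the list: Gbp2 had a log2 fold change of 2.70 ± 0.15, Iigp1 of 3.52 ± 0.22, Gbp6 of 1.87 ± 0.16 and Gbp10 of 2.06 ± 0.18 (adjusted p from 0.128 to 0.202). Gbp6 and Gbp10 are near-identical neighbours that share exons with another listed gene, so the split of reads between them is uncertain. Cfb, complement factor B of the alternative pathway, was at 45.8 ± 3.6 and 216 ± 6 RPKM, with exons shared with an overlapping gene model. Il12b, the p40 subunit of IL-12 and IL-23, was at 1.73 ± 0.45 and 12.9 ± 2.3 RPKM. Zbtb32, a zinc finger transcription factor of activated lymphocytes, had a log2 fold change of 3.08 ± 0.25. The remaining 3 were Ifi44 (2.34 ± 0.22), Apol9b (2.35 ± 0.22) and Ly6a, which encodes the surface antigen Sca-1 (1.73 ± 0.18).

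On the lower side no gene passed the adjusted threshold, and the 12 genes with the smallest p all had an adjusted p of 0.202 (limma). Il18r1, a chain of the interleukin-18 receptor, was at 19.9 ± 3.2 RPKM in saline and 2.66 ± 0.89 in polyIC libraries (SD, n = 2 per group), a log2 fold change of −2.71 ± 0.26. Cd7, a surface protein of T and NK cells, was at 31.7 ± 3.3 and 6.02 ± 2.03 RPKM. Cma1, a mast cell chymase gene that was fixed in the circulating NK and the mast cell lists, was at 21.5 ± 6.4 and 4.27 ± 0.24 RPKM. Kcnj8, a potassium channel gene, had a log2 fold change of −2.08 ± 0.19, and Fam189b one of −1.97 ± 0.17. The others were Jakmip1 (−1.75 ± 0.18), Slc26a11 (−1.69 ± 0.18), the chemokine gene Ccl17 (−1.65 ± 0.19), the diacylglycerol kinase gene Dgka (−1.57 ± 0.16), the kinesin gene Kif21b (−1.55 ± 0.18), the Myc-network repressor gene Mxd4 (−1.50 ± 0.13) and Tmem191c (−1.38 ± 0.17). Exons of Mxd4, Dgka, Cd7 and Tmem191c overlap another listed gene.

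**Figure D1:**
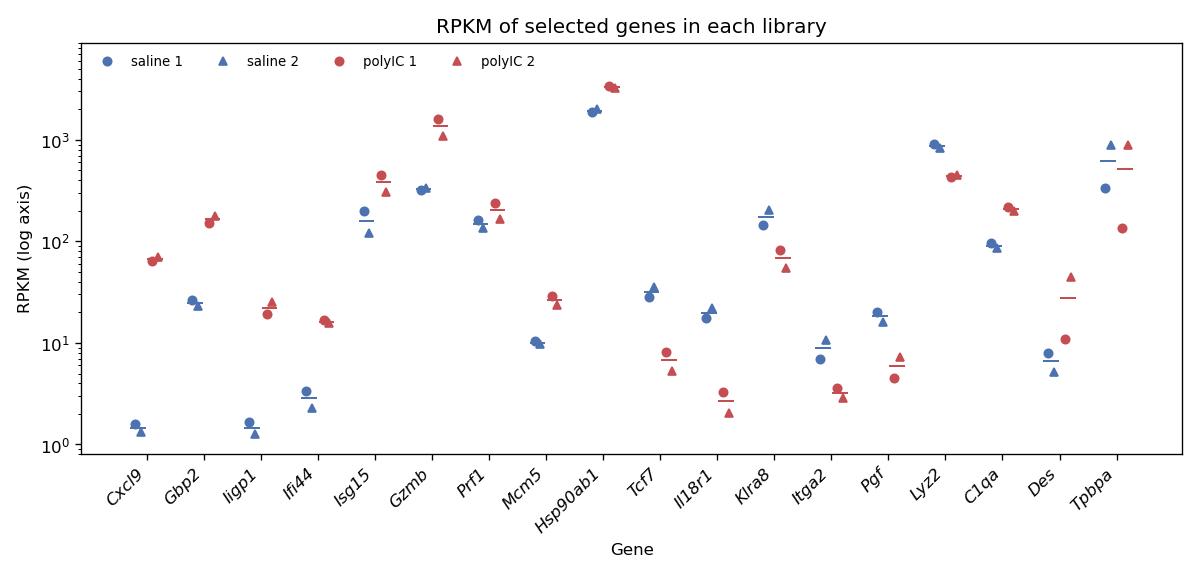
RPKM on a log axis of 18 named genes in each of the 4 libraries; circles are replicate 1, triangles replicate 2, and short lines the group means. Cxcl9 lies at 1.34 and 1.58 RPKM in saline and at 63.5 and 70.0 RPKM in polyIC libraries, while Tpbpa, a trophoblast gene, spreads from 136 to 900 RPKM between the polyIC libraries.

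Of the 36 gene lists tested, 19 passed adjusted p 0.05 in camera at the preset correlation, 10 higher and 9 lower after polyIC. None passed with an estimated correlation (smallest adjusted p = 0.654) or in fry (smallest adjusted p = 0.226). The power of these tests was not simulated. The preset test also called 17 and 15 lists when the 4 libraries were split across the groups in the other ways. Of the 19, 11 were also called in another split. In some of these the adjusted p was smaller in another split than between the groups (camera). These were NK receptors (2.06e-08), mitosis (2.95e-05), cytokine receptors (3.62e-04), RNA sensing (0.00128) and T cell markers (0.026). Trophoblast markers, not called between the groups, reached an adjusted p of 4.73e-22 in another split (camera). With an estimated correlation, the smallest adjusted p in another split was 0.306 (camera). In 18 of the 19, the exception being mitosis, the list's median in both polyIC libraries lay outside both saline libraries. In 17 the shift between the groups exceeded the shift in both other splits. The lists were called for their shift between the groups in these same libraries, so these counts are no separate support.

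Interferon-response lists rose after polyIC. The interferon-gamma list of GTPases and regulators had a median log2 fold change of 0.97 over 26 tested members (camera, adjusted p = 4.76e-12), with 21 members above 0; 1 member, Cxcl9, passed over all genes tested and 16 passed adjusted over the list alone. Gbp2 stood at 24.99 ± 2.49 RPKM in saline and 165 ± 17 in polyIC libraries, and Iigp1, an immunity-related GTPase, at 1.46 ± 0.29 and 22.1 ± 4.2 RPKM (SD, n = 2 per group). The transcription factor gene Stat1 was at 40.1 ± 2.6 and 84.1 ± 28.8 RPKM. Type I interferon-stimulated genes had a median of 0.89 over 40 members (adjusted p = 1.02e-12, camera), with 38 members above 0 and 17 past 0.05 adjusted over the list alone, none of them over all genes tested. Examples were Ifi44 (2.84 ± 0.79 and 16.2 ± 0.8 RPKM), Usp18, a protease that removes ISG15 (24.9 ± 1.0 and 65.4 ± 6.2), Lgals3bp (99.6 ± 9.0 and 222 ± 0.3) and the exonuclease gene Isg20 (46.1 ± 6.4 and 120 ± 11). Isg15 itself, a ubiquitin-like modifier, was at 160 ± 55 and 381 ± 105 RPKM. Genes of MHC class I presentation had a median of 0.61, and all 19 members were above 0 (adjusted p = 1.25e-07, camera), although none passed adjusted over the list alone. The proteasome activator genes Psme1 and Psme2 had log2 fold changes of 0.81 ± 0.20 and 0.88 ± 0.18, and the non-classical class I genes H2-T22 and H2-T23 of 0.90 ± 0.21 and 0.68 ± 0.16. For these 3 lists the adjusted p was 0.654 with an estimated correlation. Without polyIC replicate 1, the medians were lower for the type I list (0.60), the interferon-gamma list (0.64) and MHC class I (0.41). The split by replicate number, which mixes the groups, also called these 3 lists, with smaller shifts. There the type I list had a median of −0.45 (camera, adjusted p = 1.05e-09) and the interferon-gamma list one of −0.35 (adjusted p = 0.00209). MHC class I had one of −0.16 (adjusted p = 0.0296), and the remaining split called it as well (adjusted p = 0.0115, camera).

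RNA-sensing genes had a median of 0.34, with 12 of 14 members above 0 and none past 0.05 adjusted over the list alone (adjusted p = 0.00553, camera; adjusted p = 0.758 with an estimated correlation). Tlr3, the endosomal receptor for double-stranded RNA, was at 0.5001 ± 0.1810 and 2.20 ± 0.03 RPKM (SD, n = 2 per group). The cytosolic sensor gene Ifih1 had a log2 fold change of 0.84 ± 0.30, Dhx58 one of 0.83 ± 0.22 and the adaptor gene Mavs one of 0.42 ± 0.17. Without polyIC replicate 1 the call was lost, at a median of 0.15, and without polyIC replicate 2 the median was 0.56. The call was also lost among genes with a mean RPKM of at least 5 (median 0.28).

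Replication genes rose as well. The list of S phase and replication genes had a median of 0.72 over 26 members (camera, adjusted p = 2.15e-11; adjusted p = 0.654 with an estimated correlation), 24 of them above 0 and 17 past 0.05 adjusted over the list alone. Examples with a small p were the helicase subunit genes Mcm5 (log2 fold change 1.34 ± 0.16), Mcm3 (1.37 ± 0.17) and Mcm7 (1.19 ± 0.17), and Cdc45 (1.19 ± 0.16). The mitosis list had a median of 0.22 over 26 members (camera, adjusted p = 0.00713; adjusted p = 0.865 with an estimated correlation), none past 0.05 adjusted over the list alone. Its leading members were Cdk1 (0.95 ± 0.29), Tpx2 (0.81 ± 0.28), Bub1b (0.67 ± 0.22) and Top2a (0.61 ± 0.20). The proliferation marker Mki67 was at 30.3 ± 7.0 and 34.1 ± 0.4 RPKM, a difference within the spread between replicates (log2 fold change 0.19 ± 0.20). The mitosis call was lost without saline replicate 2 (median −0.02), without polyIC replicate 2 (0.17) and among genes with a mean RPKM of at least 5 (0.24), and the median was 0.45 without saline replicate 1.

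Protein-folding and metabolic lists moved too. Genes of the unfolded protein response, the endoplasmic reticulum's folding programme, rose with a median of 0.45 over 21 members, 18 above 0 and 9 past 0.05 adjusted over the list alone (camera, adjusted p = 3.90e-05). The chaperone genes Calr (1479 ± 46 and 2215 ± 205 RPKM; SD, n = 2 per group) and Pdia3 (249 ± 3 and 372 ± 3), and Sdf2l1 (23.1 ± 1.0 and 42.8 ± 3.3) and Creld2 (104 ± 14 and 162 ± 2), led it. Cholesterol synthesis genes rose with a median of 0.43 and all 17 members above 0, none past 0.05 adjusted over the list alone (camera, adjusted p = 5.54e-06). Idi1 had a log2 fold change of 1.05 ± 0.19, Cyp51 of 0.85 ± 0.22, Hmgcs1 of 0.84 ± 0.21 and Fdps of 0.75 ± 0.24. Nuclear-encoded genes of oxidative phosphorylation rose by a median of 0.20, with 22 of 26 members above 0 and none past 0.05 adjusted over the list alone (camera, adjusted p = 6.51e-04). Cycs, cytochrome c, was at 30.8 ± 1.0 and 46.6 ± 2.9 RPKM, and Ndufs3 and Cox5a had log2 fold changes of 0.71 ± 0.22 and 0.47 ± 0.16. Heat shock protein genes had a median of 0.32 over 14 members, 9 above 0 and 3 past 0.05 adjusted over the list alone (camera, adjusted p = 0.0171). Hsp90ab1 was at 1938 ± 77 and 3316 ± 147 RPKM, and the mitochondrial chaperonin genes Hspd1 and Hspe1, neighbours with overlapping exons, had log2 fold changes of 0.89 ± 0.20 and 0.86 ± 0.17. Each of these 4 lists had an adjusted p = 0.654 with an estimated correlation. The heat shock call was lost without saline replicate 1 (median 0.29) and without polyIC replicate 1 (0.11), and its median was 0.53 without polyIC replicate 2.

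Genes encoded by the mitochondrial genome fell, with a median of −0.45 over 12 members and 6 past 0.05 adjusted over the list alone, all lower (camera, adjusted p = 0.00103; adjusted p = 0.654 with an estimated correlation). mt-Nd4 was at 434 ± 17 and 239 ± 10 RPKM and mt-Nd5 at 854 ± 83 and 499 ± 26 (SD, n = 2 per group). Their neighbours mt-Nd4l, which overlaps mt-Nd4, and mt-Nd6, which overlaps mt-Nd5, had log2 fold changes of −0.87 ± 0.12 and −0.75 ± 0.13. The split of reads within each pair is uncertain. Mitochondrial genes took 0.731% and 0.687% of the reads in saline replicates 1 and 2, and 0.458% and 0.504% in polyIC replicates 1 and 2. In the same order mt-Co3, too low to be tested, had 18, 2, 22 and 12 reads. These shares may therefore miss part of the mitochondrial reads. Without polyIC replicate 1 the list's call was lost at a median of −0.31.

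Several lists of NK cell genes fell. The list of circulating NK markers had the lowest median of all, −0.79 over 15 members, with 14 members below 0 and 6 past 0.05 adjusted over the list alone (camera, adjusted p = 4.45e-06). Itga2, the integrin known as CD49b, was at 8.83 ± 2.72 and 3.23 ± 0.50 RPKM (SD, n = 2 per group), the transcription factor gene Klf2 at 27.9 ± 6.7 and 12.5 ± 1.2, and Emp3 at 27.9 ± 0.7 and 17.3 ± 0.6. NK cell receptors and adaptors had a median of −0.64, with 34 of 36 members below 0 (camera, adjusted p = 1.25e-07). None of them passed 0.05 adjusted over the list alone. This list, like others named above, had a smaller adjusted p in a split that mixes the groups (median 0.48, camera, adjusted p = 2.06e-08). That split set saline replicate 2 and polyIC replicate 1 against saline replicate 1 and polyIC replicate 2. Klra8, the activating receptor Ly49H, was at 173 ± 41 and 68.3 ± 19.2 RPKM, Klrg1 at 18.6 ± 1.9 and 10.3 ± 1.5, and Havcr2, the checkpoint receptor TIM-3, at 70.3 ± 2.7 and 43.3 ± 2.0. Reads of the Klra family may be split between near-identical members. Lag3, an inhibitory receptor gene, went the other way, from a low 0.664 ± 0.148 to 2.34 ± 0.07 RPKM. Identity regulators of NK cells and innate lymphoid cells had a median of −0.45, 15 of 16 members below 0 and 1 past 0.05 adjusted over the list alone, Tcf7 (camera, adjusted p = 4.60e-04). Tcf7, which encodes the transcription factor TCF-1, was at 31.8 ± 5.3 and 6.76 ± 2.05 RPKM. Ets1 had a log2 fold change of −1.12 ± 0.24, Il7r of −0.995 ± 0.314 and Rora of −0.77 ± 0.22, while the NK lineage factor gene Eomes was at 50.4 ± 11.2 and 31.4 ± 6.7 RPKM (−0.67 ± 0.25). For these 3 lists the adjusted p was 0.654 with an estimated correlation. The receptor median was −0.98 without polyIC replicate 1 and −0.34 without polyIC replicate 2, the library in which stromal, epithelial and trophoblast marker lists stood highest. Ncr1, which encodes NKp46, and Ptprc, which encodes CD45, had log2 fold changes of −0.56 ± 0.36 and −0.51 ± 0.31, both within 2 SE of 0.

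Chemokine and homing receptors fell with a median of −0.56, 15 of 17 members below 0 and 2 past 0.05 adjusted over the list alone (camera, adjusted p = 7.77e-04). The integrin genes Itgb7 (35.3 ± 0.1 and 19.1 ± 0.6 RPKM; SD, n = 2 per group) and Itgb2 (299 ± 1 and 224 ± 23), the chemokine receptor gene Ccr1 (12.5 ± 0.3 and 6.25 ± 1.17) and the selectin ligand gene Selplg (99.7 ± 5.6 and 61.8 ± 16.7) led it. This call was lost without polyIC replicate 2, at a median of −0.26. Cytokine receptors and feedback regulators had a median of −0.20, with 23 of 33 members below 0 and 5 past 0.05 adjusted over the list alone (camera, adjusted p = 0.0156). Il18rap, the partner chain of the interleukin-18 receptor, was at 18.1 ± 2.5 and 4.11 ± 1.56 RPKM, and the signalling genes Stat4 and Jak1 had log2 fold changes of −1.25 ± 0.24 and −0.91 ± 0.18. Its call was lost without saline replicate 1 (median −0.13) and without polyIC replicate 2 (−0.11), and the median was −0.39 without polyIC replicate 1. TGF-beta response genes fell with a median of −0.35, 12 of 14 members below 0 and none past 0.05 adjusted over the list alone (camera, adjusted p = 0.00344). Smad7 was at 26.7 ± 6.6 and 10.6 ± 1.3 RPKM, and Smad3, Ski and Bhlhe40 had log2 fold changes of −0.78 ± 0.23, −0.49 ± 0.14 and −0.48 ± 0.13. The median was −0.53 without saline replicate 2. Immediate early genes, which respond within minutes to cell stimulation or handling, fell with a median of −0.43 and all 21 members below 0, none past 0.05 adjusted over the list alone (camera, adjusted p = 3.11e-04). Egr2 was at 18.4 ± 1.9 and 7.75 ± 3.02 RPKM, Egr3 at 7.68 ± 4.22 and 2.25 ± 0.03, Nr4a2 at 95.3 ± 24.2 and 58.2 ± 6.7, and Fosl2 at 62.3 ± 5.6 and 45.5 ± 2.5. The immediate early median was −0.74 without saline replicate 1 and −0.17 without saline replicate 2. With an estimated correlation the adjusted p was 0.865 for the cytokine receptor list and 0.654 for the other 3 lists.

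The cytotoxic list did not pass (median 0.03 over 22 members, adjusted p = 0.788, camera), and its members went both ways, 11 above 0 and 11 below. Gzmb, granzyme B, was at 326 ± 12 RPKM in saline and 1363 ± 367 in polyIC libraries (SD, n = 2 per group), a log2 fold change of 2.04 ± 0.23, and was the 1 member past 0.05 adjusted over the list alone. Gzmc had a log2 fold change of 0.84 ± 0.23, Tnfsf10, which encodes the death ligand TRAIL, of 0.70 ± 0.16 and Srgn, the granule proteoglycan gene, of −0.51 ± 0.13. Prf1, perforin, was at 150 ± 19 and 204 ± 53 RPKM, a difference of about the spread between replicates. Secreted cytokines and chemokines had a median of 0.07 over 28 members (adjusted p = 0.263, camera), with 5 members higher and 1 lower past 0.05 adjusted over the list alone. Besides Cxcl9 and Il12b they included Il27 (1.23 ± 0.32 and 6.25 ± 2.18 RPKM) and the monocyte attractant gene Ccl12 (21.1 ± 2.0 and 38.4 ± 0.1). Ifng varied more between the saline libraries (9.69 ± 8.54 RPKM) than between the groups (9.23 ± 1.84 in polyIC). Tnf was at 129 ± 12 and 75.7 ± 0.8 RPKM, Il10 at 8.91 ± 2.91 and 11.4 ± 4.0, and Il15 at 1.32 ± 0.13 and 1.63 ± 0.22.

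Growth and angiogenic factors, through which decidual NK cells are known to act on uterine vessels, did not pass as a list (median −0.23 over 17 members, mean 0.03, adjusted p = 0.792, camera). Pgf, placental growth factor, was at 18.3 ± 2.9 and 5.925 ± 1.998 RPKM (SD, n = 2 per group), a log2 fold change of −1.58 ± 0.28, and the urokinase gene Plau at 65.2 ± 12.4 and 43.9 ± 3.9. Vegfa was at 206 ± 68 and 155 ± 17 RPKM, within the spread between the saline libraries. Adm, adrenomedullin, was at 7.61 ± 0.64 and 23.7 ± 15.5 RPKM, and Ptn at 3.11 ± 1.21 and 6.94 ± 3.68. The list's median was −0.03 without saline replicate 1, 0.22 without polyIC replicate 1 and −0.15 without polyIC replicate 2. Tissue-resident NK markers had a median of −0.22 over 15 members (adjusted p = 0.226, camera), with Itga1, which encodes CD49a, at 9.04 ± 0.92 and 6.31 ± 0.35 RPKM and Cd200r1 at 5.79 ± 0.25 and 3.504 ± 0.116. Their median was −0.57 without saline replicate 1, −0.48 without polyIC replicate 1 and 0.01 without polyIC replicate 2. Of the 17 lists that did not pass, 16 changed the sign of their median when 1 library was left out, the exception being neutrophil markers, whose median turned to 0.10 with no filter on low values.

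Among the other lists that did not pass, NF-kB targets had a median of −0.13 (adjusted p = 0.263, camera), with Ptgs2 at −0.61 ± 0.15, Icam1 at 0.66 ± 0.16 and Bcl2a1a at 0.91 ± 0.30. Apoptosis genes had a median of 0.06 (adjusted p = 0.236), and Mlkl, the effector of necroptosis, was at 22.5 ± 3.0 and 52.0 ± 4.3 RPKM (SD, n = 2 per group). Mlkl was the 1 member past 0.05 adjusted over that list alone, and Bax, Casp3 and Casp4 had log2 fold changes of 0.56 ± 0.14, 0.64 ± 0.17 and 0.44 ± 0.16. Glycolysis genes had a median of 0.02 (adjusted p = 0.571), with Ldha at 0.48 ± 0.14, Pfkl at 0.35 ± 0.13, Gapdh at 0.26 ± 0.13 and Slc2a3 at −0.71 ± 0.22. Cytosolic ribosomal proteins had a median of −0.03 (adjusted p = 0.507), with Rps2 at 0.46 ± 0.15 and Rps11 at −0.38 ± 0.16. NF-kB targets passed without saline replicate 2 (median −0.28), and apoptosis genes without polyIC replicate 2 (0.21).

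**Figure D2:**
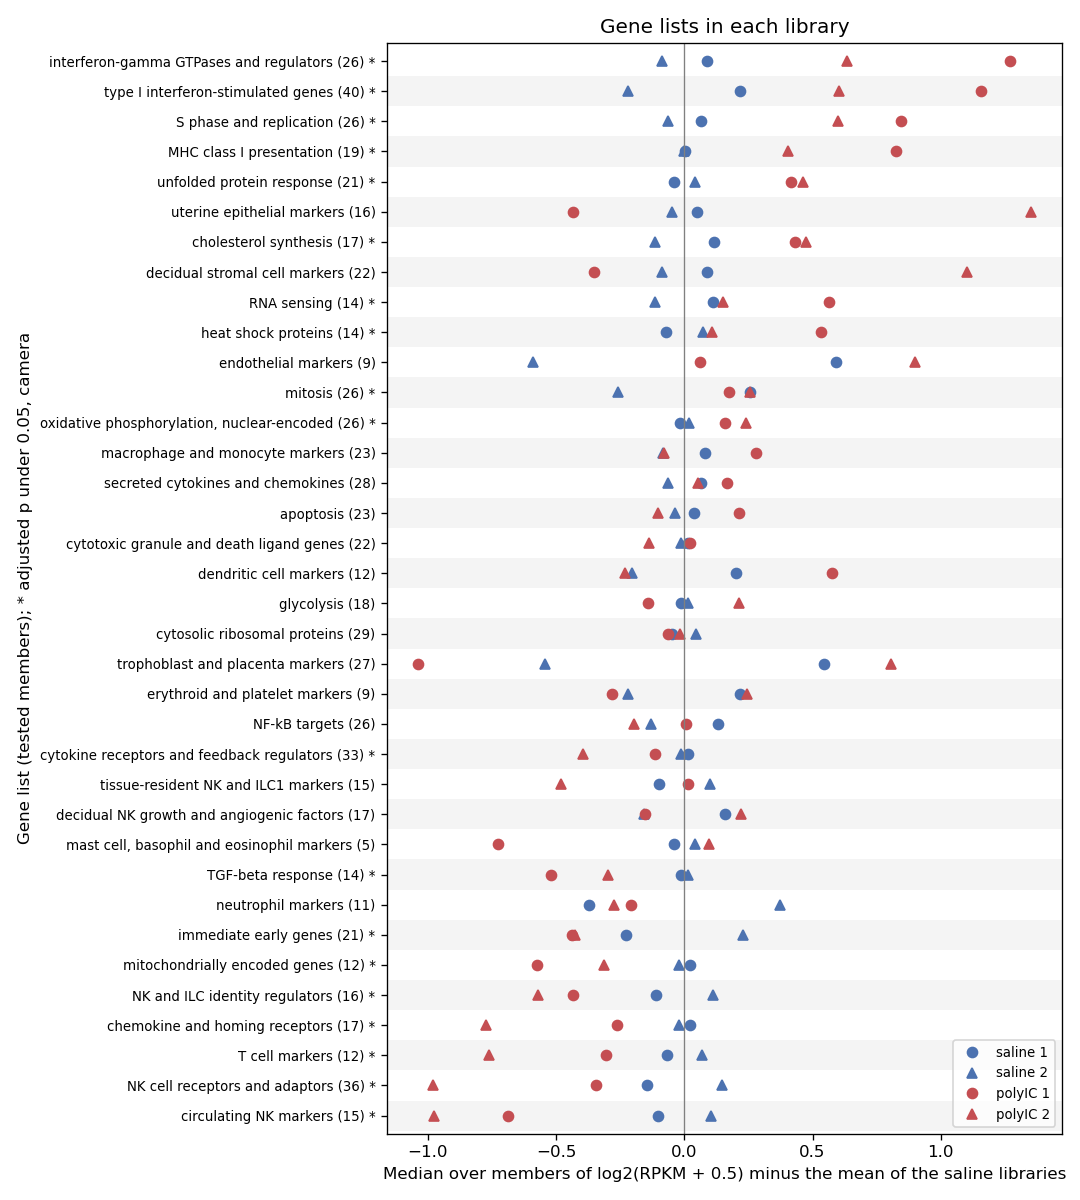
Median over the members of each gene list of log2(RPKM + 0.5) minus the mean of the saline libraries, for each of the 4 libraries, with lists ordered by the median log2 fold change and called lists starred. In the interferon-gamma list the polyIC libraries stand at 1.27 and 0.64, whereas in the trophoblast list they stand at −1.04 and 0.80, on either side of the saline libraries.

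Tpbpa, Krt8 and Krt18, markers of other cells of the implantation site, were at 105 RPKM or more in every library. Trophoblast markers had a median of −0.05 over 27 members (adjusted p = 0.983, camera) and parted the polyIC libraries, at −1.04 in replicate 1 and 0.80 in replicate 2 against the saline mean. The trophoblast median was 0.80 without polyIC replicate 1, −1.04 without polyIC replicate 2, 0.58 without saline replicate 1 and −0.28 without saline replicate 2, each past the threshold. Tpbpa was at 335 and 892 RPKM in saline, and at 136 and 900 RPKM in polyIC libraries. The prolactin family gene Prl8a9 was at 478 ± 29 and 358 ± 377 RPKM (SD, n = 2 per group). Decidual stromal markers (median 0.39 over 22 members, adjusted p = 0.104) stood at −0.35 in polyIC replicate 1 and 1.10 in replicate 2, and uterine epithelial markers (0.45 over 16 members, adjusted p = 0.104) at −0.43 and 1.35. Both lists passed without polyIC replicate 1, at medians of 1.10 and 1.35, and with values rescaled to a common total (0.40 and 0.43), where 16622 genes were tested. The stromal list also passed without saline replicate 1 (0.46) and with no filter on low values (0.33). Des, desmin, was at 10.9 RPKM in polyIC replicate 1 and 45.04 in replicate 2, Vim, vimentin, at 217 and 509, Krt8 at 110 and 417 and Krt18 at 105 and 351. In the saline libraries Vim was at 612 and 652 RPKM, above both polyIC libraries. Endothelial markers had a median of 0.26 over 9 members (adjusted p = 0.337), with Pecam1 at 16.1 ± 3.2 and 16.2 ± 1.8 RPKM, and passed without saline replicate 1 at a median of 1.17.

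Macrophage and monocyte markers had a median of 0.10 over 23 members (adjusted p = 0.543, camera), with 6 members higher and 5 lower at an unadjusted p under 0.05, and 2 higher and 3 lower past 0.05 adjusted over the list alone. The complement genes C1qa (90.6 ± 7.3 and 209 ± 16 RPKM; SD, n = 2 per group) and C1qc (27.4 ± 3.4 and 54.3 ± 9.3) were higher, and Lyz2, lysozyme (874 ± 53 and 441 ± 19), and Mrc1, the mannose receptor (15.8 ± 1.6 and 7.67 ± 1.18), lower, past that adjustment over the list. Apoe, at 1805 ± 108 and 1337 ± 93 RPKM, did not pass it (adjusted p = 0.0736 over the list alone). Dendritic cell markers had a median of 0.03 (adjusted p = 0.329), with H2-Ab1 at 924 ± 283 and 777 ± 514 RPKM and Bst2, which is also an interferon-stimulated gene, at 124 ± 13 and 261 ± 20. Neutrophil markers had a median of −0.40 and a mean of 0.05 (adjusted p = 0.761), with Cxcl2 at 499 ± 178 and 301 ± 138 RPKM and S100a9 at 264 ± 135 and 167 ± 26. T cell markers fell with a median of −0.60, 9 of 12 members below 0 and none past 0.05 adjusted over the list alone (camera, adjusted p = 0.0395; adjusted p = 0.782 with an estimated correlation). Trbc1 was at 75.7 ± 12.2 and 48.1 ± 14.3 RPKM and Cd3d at 3.95 ± 0.91 and 2.04 ± 0.52, while Ctla4, an inhibitory receptor gene, was at 15.6 ± 4.3 and 31.0 ± 5.2. That call was lost without saline replicate 2 (median −0.46), without polyIC replicate 2 (−0.30) and with values rescaled to a common total (−0.56), a fit on 16622 genes. With a mean RPKM of at least 5 the list had too few members to be tested. With no filter on low values the median was −0.35. Mast cell, basophil and eosinophil markers had a median of −0.23 over 5 members (adjusted p = 0.158), and erythroid and platelet markers one of −0.07 and a mean of 0.06 over 9 members (adjusted p = 0.545), with Hbb-bs at 110 ± 52 and 74.8 ± 12.7 RPKM. Without polyIC replicate 2, dendritic cell markers (median 0.57) and mast cell, basophil and eosinophil markers (−0.73) passed. B cell and plasma cell markers had 2 tested members, Ighm (28.5 ± 4.3 and 17.3 ± 5.7 RPKM) and Igkc (12.5 ± 4.9 and 5.27 ± 1.23), and Y-linked genes had 0 of 4, so neither list was tested.

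The 5 entries with the highest mean RPKM were Gm25745 (7793 ± 867 and 11724 ± 1265 RPKM; SD, n = 2 per group), Gm27597, Gm27786, Gm23419 and Gm10925. The first 4 of these lie in exons of Hsp90b1, Rpl19, H19 and Actg1, so their RPKM may count reads of those genes.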

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

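Voom on the recovered reads was chosen after the data were seen; the other alternatives were fixed before. The planned test on raw counts was not run, because the table holds RPKM. The count of genes past adjusted p 0.05 (1, Cxcl9) was 2 with a pseudocount of 1 and with protein-coding genes alone (Cxcl9 and Saa3), and 0 with no filter on low values, with no variance trend, with voom on recovered reads and in each fit that left out a library (range 0 to 0). With a threshold of 1 on the absolute log2 fold change it was 1. With no filter the adjustment runs over more genes, which makes it stricter. Without a library fewer samples are left, and the residual spread comes from the pair of the other group alone. The cause of the other changes was not tested. The deviations of the replicates numbered 1 had a correlation of −0.048 across genes, so no pairing by replicate number was seen over all genes. A pairing that affects part of the genes is not excluded. With the replicate number as a replicate block, 0 genes passed (Cxcl9 adjusted p = 0.304) and 21 lists passed, the called 19 and the stromal and epithelial markers. With a mean RPKM of at least 5, fewer genes were tested and 620 were lower at an unadjusted p under 0.05, against 1031. Leaving out a library gave 406 to 1555 higher and 304 to 1587 lower genes at that threshold. The share of higher genes among them was 48.1% to 56.6% under the other filters and scalings, against 52.1%. The median log2 fold change of all genes was −0.02, and under the other scalings it lay between −0.05 and −0.007.

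Calls of gene lists turned on how the correlation between genes was treated. At the preset correlation 19 lists passed, and 0 passed with an estimated correlation or in fry, with the medians unchanged by construction: type I interferon-stimulated genes 0.89, interferon-gamma 0.97, MHC class I 0.61, RNA sensing 0.34, S phase 0.72, mitosis 0.22, oxidative phosphorylation 0.20, cholesterol synthesis 0.43, unfolded protein response 0.45, heat shock 0.32, NK receptors −0.64, NK identity regulators −0.45, circulating NK markers −0.79, cytokine receptors −0.20, mitochondrially encoded −0.45, immediate early −0.43, TGF-beta response −0.35, homing receptors −0.56 and T cell markers −0.60. With a mean RPKM of at least 5, 16 of the 19 calls were kept: those of RNA sensing (0.28) and mitosis (0.24) were lost, and T cell markers had too few members left to be tested. With values rescaled to a common total the call of T cell markers was lost (−0.56); that fit tested 16622 genes against 13523, so the effects of scaling and of the genes tested are not separated. Under the other pseudocounts, scalings and variance models and voom all 19 kept their call and direction.

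Leaving out each library in turn kept 15 to 17 of the 19. Calls were lost for cytokine receptors and heat shock without saline replicate 1, for mitosis and T cell markers without saline replicate 2, for RNA sensing, heat shock and mitochondrially encoded genes without polyIC replicate 1, and for cytokine receptors, mitosis, homing receptors and T cell markers without polyIC replicate 2. The medians ranged from 0.15 to 0.56 for RNA sensing, 0.11 to 0.53 for heat shock, −0.57 to −0.31 for mitochondrially encoded genes, −0.39 to −0.11 for cytokine receptors, −0.77 to −0.26 for homing receptors and −0.76 to −0.30 for T cell markers, each losing its call in at least 1 of these fits. Mitosis ranged from −0.0195 to 0.45 and trophoblast markers from −1.04 to 0.80, so both changed sign. The shallowest library held 25286670 reads.

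Among the log2 fold changes of the named genes, 2733 values kept direction and call status, and 31 changed sign with no call either way. A call was lost in 8, all of Cxcl9, and gained in 1, of Saa3 with a pseudocount of 1. Cxcl9 alone had a call to lose, so the other kept values stayed uncalled. Most named genes were picked by their values in these same libraries, so a kept direction is no separate support. The fit on protein-coding genes alone, where Saa3 passed as well, is not in this tally.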

Other observations

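All tests in this part other than those of GC content, gene length, depth and splits of the libraries were chosen after the result was seen.

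Some listed genes were too low to be tested but differed in their reads, and are named after their values were seen. Cd19, a B cell surface gene, had 117 and 60 reads in saline replicates 1 and 2, and 13 and 2 reads in polyIC replicates 1 and 2. Ms4a1, which encodes CD20, had 54, 32, 16 and 8 reads in the same order. Ido1, an interferon-inducible enzyme of tryptophan breakdown, had 28 reads in polyIC replicate 2 and was listed at 0 in the other libraries. The Y-linked gene Ddx3y, which maternal cells lack, had 108, 40, 49 and 146 reads, so that it stood highest in saline replicate 1 and polyIC replicate 2.

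Ribosome biogenesis genes were not among the fixed lists. Fbl, Ncl and Pa2g4 had been seen to be higher, and the hypothesis was that nucleolar genes as a group went up in the libraries in which replication and chaperone genes did. Over the 33 tested genes of a list without those 3, the median log2 fold change was 0.71, and 33 of 33 lay above 0. In camera at the preset correlation the adjusted p was 1.18e-20 (limma), while it was 0.634 with an estimated correlation, and 29 genes passed 0.05 adjusted over the list alone. The list's median stood at 0.76 and 0.66 in the polyIC libraries and within 0.01 of the saline mean in both saline libraries. Nop16 was at 19.4 ± 0.2 and 39.8 ± 1.8 RPKM (SD, n = 2 per group), Mybbp1a at 33.6 ± 0.1 and 66.7 ± 3.3, and Nolc1 at 79.2 ± 3.6 and 154 ± 4. The pattern was found and tested on the same libraries and stays a hypothesis.

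The 19 list calls were weighed against technical explanations. After each library's trend with GC content and gene length was removed, 19 of 19 kept their call and direction, although the correction moved the log2 fold changes by a median of 0.0625, and the other splits called at most 7 of these lists in a matching direction. This argues against that trend as the whole cause, but not as a part of it: the called medians became 0.483 to 1.14 of their size, the smallest being that of cytokine receptors, now −0.095. With all libraries thinned to the reads of the shallowest, 19 kept call and direction, as had been set beforehand for a pattern that depth does not cause. That thinning moved the log2 fold changes by a median of 0.0114, above the bound of 0.01 used for GC content and tried first here. A later comparison with a second thinning gave a median difference of 0.0156 between the 2, so the move was no more than resampling noise. The values were already scaled per library, so the thinning decides nothing about depth, which stays open. Of the 3 splits of the 4 libraries into pairs, 1 gave as many lists, the real split with 19, and the highest other gave 17; with 3 splits no share under 0.05 can be had. The other splits gave 370 and 425 genes at an unadjusted p under 0.05 against 2152, so the preset test of lists also responds to differences between libraries other than the groups.

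More macrophages and monocytes in the polyIC isolates are a candidate explanation for the higher interferon-gamma list, as these cells respond strongly to interferon. Added cells would bring all their abundant transcripts, but the 5 most abundant markers had a median log2 fold change of −0.11 (SD 0.93), below the list's 0.97: Apoe was at −0.43, Lyz2 at −0.99, Cd68 at −0.11, C1qa at 1.198 and C1qb at 0.98. Of the macrophage list's 23 tested genes, 4 stand in another list as well. The marker values argue against added cells as the whole source only if such cells had the marker levels of those in the saline isolates. Added cells with other marker levels stay open, since the 5 markers went both ways. A changed state of macrophages already in the isolates, and a response of the NK cells themselves, stay open too.

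RNA of stromal, epithelial and placental cells could have lowered the NK receptor and circulating NK lists by dilution, and polyIC replicate 2 had the highest levels of those markers. Without that library the receptor median was −0.34 and the circulating NK median −0.69. That fit rests on polyIC replicate 1, where the stromal, epithelial and trophoblast medians lay below the saline mean at −0.35, −0.43 and −1.04. A single library excludes nothing, and the NK share of the isolates is not given in the sources used here, so dilution and lower expression in NK cells cannot be told apart.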
